A study of Mus musculus with 2 samples.

How the data were processed

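Total RNA was sequenced from midbrain of mouse embryos of the B6NCrl strain, a C57BL/6 substrain, at embryonic day 15.5. Each of the 2 libraries came from its own pool of embryos of both sexes, with 78 embryos in replicate 1 and 62 in replicate 2. Per the labels, the RNA was extracted with the mirVana kit, the RNA used was longer than 200 nt, 10 ng entered each library and ERCC spike-in RNA had been added. The protocol links in the labels include the manual of a low-input cDNA kit. PCR copies of 1 molecule could not be told apart in the values used here, so counting intervals and floors cover counting error only.

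For each library the authors deposited a gene table and a transcript table. Per the file headers, the gene tables hold expected counts, TPM (abundance by length-scaled share of transcripts) and FPKM (fragments scaled by effective length and library size), and posterior means and posterior SDs of the same quantities. The transcript tables add, per the file headers, the percent of its gene's abundance that each transcript takes. The deposited TPM values were scaled over all rows of a table, spike-ins included. The genome build was mm10 and the annotation was GENCODE release M4, per the authors' notes deposited beside the tables. The aligner and the counting tool, their versions and the use of read strand are not given in the sources used here. Length minus effective length was 99 nt within 0.02 in 41286 of 41288 rows with an effective length above 0, so features shorter than 100 nt carried a TPM of 0. TPM of genes only slightly longer rests on a very short effective length.

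Of the 69691 rows of a gene table, 43346 carried an Ensembl gene ID, 96 were spike-ins, 1 was the phiX genome and 26248 had only a number as ID. The number rows were left out of all comparisons; they took 5.5e-05% of the expected counts in replicate 1 and 3.0e-05% in replicate 2, and 26185 of them were shorter than 100 nt. Spike-ins took 2.30% and 2.42% of the counts and entered no test or library size. Symbols were matched by gene ID without its version, and 42462 of the 43346 genes had one. Biotypes, transcript names and coordinates were taken from GENCODE M21 on the same build. The symbols Ahsp and Sox2ot of the gene lists were not matched and were left out.

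The tables summed to 38966386 expected counts in replicate 1 and 40419493 in replicate 2, most of which fell on Ensembl genes. At this depth 3 counts, taken as the limit that a count of 0 allows, equal 0.143 TPM in replicate 1 and 0.138 TPM in replicate 2 for a gene 1000 nt long. Genes at 1 TPM or more in both libraries were called expressed. Levels are means ± SD of the 2 libraries (n = 2) in TPM, and list medians on a log scale used log2(TPM + 1), which understates ratios of low genes. A difference between lists was taken within each library, then averaged. Its SD describes how far the 2 pools differ, not the spread among the members of a list. A difference above its SD therefore does not show that 2 lists differ beyond the spread of their genes. With 2 libraries the smallest two-sided p of an exact sign-flip test is 0.5, so no p was given for such differences.

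The 2 libraries were compared with a two-sided exact binomial test per gene on expected counts rounded to whole numbers, conditional on their sum. The expected share came from TMM library sizes (edgeR 4.0.16 in R 4.3.3). P-values were adjusted by Benjamini and Hochberg over the genes with a mean of 10 or more counts, and a gene passed at an adjusted p under 0.05 and at least a 2-fold difference. Such p-values compare these 2 libraries, not conditions, and there was no further library to check a difference with. The biological coefficient of variation was edgeR's common dispersion in a fit with an intercept only. Gene lists were compared between the libraries by the median log2 ratio of their members with a mean of 10 or more counts. That median was placed among 10000 random lists of equal size drawn from the 200 genes nearest in mean count, as a description of these libraries. Read assignment was called ambiguous where the posterior SD of a gene's count was over 10% of its posterior mean in either library. A log2 ratio used 0.5 added to each rounded count. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.

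The tests were checked on simulated data drawn from the real mean counts and library sizes with 200 changed genes. For replicate 2 against replicate 1 with counting noise only, over 18289 genes tested, 94 of 100 genes changed 4-fold and 89 of 100 changed 3-fold were recovered, and 3 unchanged genes passed. With the estimated spread between the libraries added, over 18291 genes tested, 97 and 95 of 100 were recovered and 29 unchanged genes passed. Simulated coefficients of variation of 0.05 and 0.1 came back as 0.0495 and 0.0996 over 18269 genes. Of 100 random lists of 10 genes, 6 fell outside the middle 95% of their random lists.

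The gene lists were fixed before the data were examined: 34 lists of marker genes and 3 defined by symbol. They covered midbrain, telencephalic, diencephalic, Hox, and isthmic and cerebellar genes, 6 transmitter classes, secreted patterning and ephrin genes, progenitors, neurogenesis, proliferation, immature and mature neurons, oligodendrocyte precursors, myelin and astrocytes. They also covered microglia, endothelium, mural cells, meninges, blood, choroid plexus, muscle, cartilage and skin, immediate early, heat shock, hypoxia and sex-linked genes, long noncoding RNAs, structural small RNAs, mitochondrially encoded genes, histones and ribosomal proteins. The symbol pattern for histones was meant for replication-dependent ones but also took the replication-independent linker histone genes H1f0, H1fx, H1fnt and H1foo and a pseudogene, Hist3h2bb-ps. Ribosomal protein S6 kinases, whose symbols begin like ribosomal proteins, were left out of the ribosomal list. Named genes followed a rule fixed at the same time. From each list the text names at most the 4 highest members and members below the threshold that a count calls for; it adds the 10 highest genes of all, the 5 largest ratios in each direction among genes passing with a mean of 50 or more counts, and 10 genes for isoforms. Beyond this rule, some list members were named because they passed the test between the libraries, over all genes or over their list alone. Gm10925 was named for its position beside Gm28437. Other genes outside this rule are said to have been chosen after their values were seen. Alternatives covered thresholds, pseudocounts, units, scaling (DESeq2 1.42.0 size factors among them), filters, the test and each replicate left out.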

Results

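The midbrain of mouse embryos at embryonic day 15.5 was profiled by total RNA sequencing in 2 biological replicates, each a pool of embryos of both sexes (78 embryos in replicate 1 and 62 in replicate 2). The design had 1 tissue and 1 age. The comparisons it allows are therefore between groups of genes within the tissue and between the 2 pools. The libraries held 38966386 and 40419493 expected counts. Genes at 1 TPM or more numbered 15881 in replicate 1 and 15900 in replicate 2, and 15347 of them passed in both, of which 13401 were protein coding. At 100 TPM or more in both libraries there were 1717 genes, and at 1000 TPM or more 76. All levels below are means ± SD of the 2 libraries (n = 2) in TPM.

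The tissue's most abundant RNAs were the signal recognition particle RNAs Rn7s1 (17315 ± 335) and Rn7s2 (17314 ± 333), near-identical copies on chromosome 12 (69159295 to 69159594 and 69361182 to 69361481, mm10) between which reads could not be assigned with certainty. Next came Tuba1a (16021 ± 152; chromosome 15, 98949837 to 98953703), the alpha-tubulin isotype of newborn neurons, and Nnat (8766 ± 155; chromosome 2, 157560078 to 157562522), an imprinted gene for a small membrane proteolipid. The other genes among the 10 highest were Gm28437 (8176 ± 25.4), Malat1 (7794 ± 1057), mt-Atp6 (7317 ± 229), Stmn1 (6205 ± 61.8), Hba-a2 (5945 ± 1035) and Actb (5620.3 ± 8.25). Gm28437 is an annotated pseudogene on chromosome 1, and its read assignment was ambiguous, as was that of mt-Atp6, the gene of an ATP synthase subunit. Malat1 is a nuclear long noncoding RNA, Stmn1 a microtubule-destabilising protein gene, Hba-a2 an adult alpha-globin gene and Actb beta-actin. The 10 highest genes took 10.1% of TPM in replicate 1 and 10.0% in replicate 2. Mitochondrially encoded genes took 3.02% and 3.29%, with 15 of 37 expressed and a median of 1372 ± 194 among those 15. The mitochondrial tRNAs are shorter than 100 nt and were not measurable here. This share may miss reads of mitochondrial RNA that were assigned elsewhere. Gm28437 (24613189 to 24613971) lies beside Gm10925 (24613974 to 24614651), a mitochondrial-like pseudogene. Expressed unprocessed pseudogenes took 1.68% of TPM in replicate 1 and 1.80% in replicate 2. TPM of short RNAs rests on short effective lengths, so ranks against long genes are approximate. The limit applies to Malat1 as well, whose effective length was 421 nt although the gene spans 5795690 to 5802672 on chromosome 19.

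Genes of young postmitotic neurons were the most abundant of the marker lists. All 11 of the list were expressed, with a median of 643 ± 27.4 TPM. They included Stmn1 (6205 ± 61.8), Tubb3 (1757 ± 36.6), Gap43 (1239 ± 41.7) and Dpysl3 (1032 ± 11.8), which encode microtubule and growth cone proteins. Genes of mature neurons, with 13 of 13 expressed, had a median of 43.6 ± 0.0919 TPM, led by the neurofilament gene Nefl (216 ± 8.44), the AMPA receptor subunit gene Gria2 (171 ± 13.8) and the synaptic vesicle fusion genes Snap25 (126 ± 7.35) and Syt1 (95.3 ± 4.45). Radial glia and progenitor genes were expressed in 13 of 13 cases at a median of 29.5 ± 4.44 TPM, led by the fatty acid binding protein gene Fabp7 (976 ± 17.9), Vim (335 ± 13) for an intermediate filament, the Notch target Hes5 (108 ± 19.6) and the glutamate transporter gene Slc1a3 (84.3 ± 3.82). Proliferation genes (11 of 11 expressed) had a median of 26.4 ± 1.75 TPM, with the replication clamp gene Pcna at 77.3 ± 3.06 and the mitotic kinase gene Cdk1 at 52.5 ± 2.26. Proneural and other neurogenic transcription factors (7 of 7 expressed) had a median of 4.29 ± 1.15 TPM, and the highest were Neurod1 (17.3 ± 0.354) and Neurog2 (12.9 ± 0.884). On the log2(TPM + 1) scale the immature neuron median lay above that of mature neuron genes by 3.85 ± 0.06, above radial glia and progenitor genes by 4.41 ± 0.27 and above proliferation genes by 4.56 ± 0.15. Each of these differences exceeded its SD between the libraries and had the same sign in both; levels of different genes also depend on length and on how many cells express them.

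Transcription factors that mark the midbrain were expressed at moderate levels (8 of 9, median 9.34 ± 0.120 TPM). The highest were the homeobox genes Meis2 (66.4 ± 7.51) and Otx2 (66.2 ± 0.177), followed by the paired box gene Pax3 (10.6 ± 1.85) and Otx1 (9.70 ± 0.389), and En2 (0.985 ± 0.318) was under the threshold in replicate 2. Hox genes, which pattern the hindbrain and spinal cord, were expressed in 0 of 14 cases; the highest were Hoxb5 (0.320 ± 0.354) and Hoxa5 (0.275 ± 0.361), and Hoxa4, Hoxb4 and Hoxb8 were listed at 0 in both libraries. Genes listed for neighbouring regions were expressed as well, but whether their RNA came from those regions or from midbrain cells was not tested. Telencephalic transcription factors were expressed in 11 of 12 cases (median 4.91 ± 0.675 TPM), led by Dlx1 (40.8 ± 6.93), Neurod6 (16.3 ± 3.06), Emx2 (13.8 ± 1.47) and Dlx5 (13.7 ± 2.24). Diencephalic genes were expressed in 7 of 10 cases (median 10.1 ± 0.375 TPM), among them the homeobox gene Lhx9 (106 ± 10.2), the vasopressin gene Avp (55.6 ± 15.3), Six3 (24.8 ± 0.290) and Gbx2 (17.4 ± 3.09). Isthmic and cerebellar genes were expressed in 6 of 10 cases (median 1.64 ± 0.258 TPM), led by Barhl1 (54.0 ± 14.4) and Pax5 (7.29 ± 0.841). The midbrain median exceeded the telencephalic one by 0.83 ± 0.17 log2 units and the Hox one by 3.31 ± 0.04, both more than the SD between the libraries. That SD leaves out the spread among members, which ran from 0.985 to 66.4 TPM for midbrain and 0.83 to 40.8 TPM for telencephalic factors. The difference to the Hox genes became 6.06 with a pseudocount of 0.1, since the Hox levels lay near 0.

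Among transmitter classes the GABAergic genes were highest, with 8 of 8 expressed and a median of 60.5 ± 6.94 TPM. The GABA-synthesising enzyme gene Gad1 stood at 98.4 ± 8.58, and the transcription factor genes Gata3 and Sox14 at 88.0 ± 9.27 and 67.3 ± 8.88. Glutamatergic genes (4 of 5 expressed) had a median of 14.4 ± 2.06 TPM, with the vesicular glutamate transporter gene Slc17a6 at 83.3 ± 0.559, the POU factor genes Pou4f1 at 55.7 ± 2.97 and Pou4f2 at 14.4 ± 2.06, and Slc17a7 below the threshold (0.560 ± 0.170). All 14 dopaminergic genes were expressed (median 7.09 ± 0.933 TPM), led by the nuclear receptor gene Nr4a2 (32.9 ± 0.304), the tyrosine hydroxylase gene Th (28.6 ± 0.509), the vesicular monoamine transporter gene Slc18a2 (19.9 ± 3.44) and Ddc (16.9 ± 0.318). The 4 serotonergic genes were expressed at a median of 3.31 ± 0.488 TPM, with the tryptophan hydroxylase gene Tph2 at 4.87 ± 1.56 and the serotonin transporter gene Slc6a4 at 4.67 ± 0.0354. Of the cholinergic motor genes, 3 of 5 were expressed (median 1.68 ± 0.184 TPM), with Isl1 at 26.5 ± 2.02, and of the noradrenergic genes 0 of 4 in both libraries (median 1.32 ± 1.03 TPM). The GABAergic median exceeded the glutamatergic one by 2.00 ± 0.35 log2 units and the dopaminergic one exceeded the serotonergic one by 0.92 ± 0.01, more than the SD in each case. The first difference was 1.05 when members below the threshold were left out.

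Glial lineages were represented at lower levels than neurons. Oligodendrocyte precursor genes (6 of 6 expressed, median 7.45 ± 0.894 TPM) were led by the transcription factor genes Olig1 (65.8 ± 1.73) and Olig2 (8.97 ± 0.212) and the growth factor receptor gene Pdgfra (8.46 ± 0.0212). Myelin genes (5 of 6 expressed, median 5.84 ± 0.456 TPM) were led by Cnp (32.0 ± 1.22) and Mbp (15.8 ± 0.396), and Mobp was almost undetected (0.0150 ± 0.0212). Astrocyte genes (7 of 9 expressed, median 14.7 ± 0.940 TPM) were led by the apolipoprotein gene Apoe (363 ± 75.4), the gap junction gene Gja1 (96.8 ± 11) and Aldoc (88.5 ± 26.4), while the intermediate filament gene Gfap was below the threshold (0.160 ± 0.0566). The precursor median exceeded the myelin median by 0.43 ± 0.09 log2 units, and the radial glia median the astrocyte median by 0.95 ± 0.30. Both differences exceeded their SD, but over expressed members alone they changed sign, to -0.23 and -0.57.

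Other cell types contributed RNA too. Microglia and macrophage genes (11 of 12 expressed, median 10.6 ± 1.14 TPM) included C1qb (36.3 ± 5.61), Tyrobp (26.2 ± 5.33) and C1qa (23.9 ± 4.91), the first and last of which encode complement subunits. Their median lay 5.88 ± 0.17 log2 units below that of immature neuron genes. Endothelial genes (10 of 10 expressed, median 13.6 ± 0.757 TPM) included the tight junction gene Cldn5 (97.7 ± 14.9) and the glucose transporter gene Slc2a1 (85.1 ± 2.34), and mural cell genes (8 of 8 expressed, median 12.4 ± 0.704 TPM) Vtn (132 ± 28.2) and the receptor gene Pdgfrb (14.8 ± 0.849). Endothelial and mural medians differed by 0.14 ± 0.0028 log2 units, and by 0.70 when list means replaced medians. Meningeal and fibroblast genes (9 of 9 expressed, median 51.6 ± 6.25 TPM) were led by the collagen gene Col3a1 (153 ± 13.3) and the growth factor gene Igf2 (116 ± 18.6). Erythroid genes (10 of 10 expressed, median 92.3 ± 15.6 TPM) took 1.49% of TPM in replicate 1 and 1.17% in replicate 2, and the globin genes Hba-a2, Hbb-bs (3025 ± 594), Hba-a1 (2253 ± 379.6) and Hbb-bt (1883 ± 282) led them. Choroid plexus genes (6 of 7 expressed, median 3.86 ± 0.269 TPM) were led by the transthyretin gene Ttr (253 ± 22.6). Of the muscle, cartilage and skin genes 4 of 10 were expressed in both libraries, and the list median was 0.145 TPM in replicate 1 and 3.53 TPM in replicate 2. Krt5 rose from 0.08 to 4.72 TPM and Krt14 from 0.21 to 5.02 TPM across the middle of the list. The median log2 count ratio over the 7 tested members was 0.13, inside the range of random lists, so the list median does not show a shift of the whole list.

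Further lists described signalling, stress and RNA classes. All 13 ephrin and Eph receptor genes, which guide axons, were expressed (median 32.6 ± 2.05 TPM), led by Efnb3 (149.9 ± 6.87), Ephb1 (74.2 ± 2.26), Epha7 (58.2 ± 8.67) and Efna5 (55.0 ± 8.87). Ventral midline and secreted patterning genes (5 of 7 expressed, median 11.9 ± 1.04 TPM) included Spon1 (35.5 ± 4.93), Slit2 (22.1 ± 0.537) and Ntn1 (18.7 ± 0.163). Immediate early genes, which respond to activity and handling, were low (8 of 11 expressed, median 2.58 ± 0.170 TPM), with the highest, Jun, at 42.4 ± 2.60. Heat shock genes (4 of 5 expressed) were led by the chaperone gene Hsp90aa1 (1173 ± 7.21; list median 70.9 ± 0.856 TPM), and hypoxia genes (6 of 6 expressed) by the lactate dehydrogenase gene Ldha (452 ± 40.2; list median 11.2 ± 0.559 TPM). Both sexes were visible, with the X-inactivation RNA Xist at 25.6 ± 0.643 and the Y-linked gene Eif2s3y at 31.3 ± 3.62 (list median 11.4 ± 0.262 TPM, 5 of 5 expressed). Long noncoding RNAs (9 of 9 expressed, median 54.2 ± 1.65 TPM) were led by Malat1, Meg3 (1847 ± 117) and Snhg11 (492 ± 60.3). Cytoplasmic ribosomal protein genes had a median of 337 ± 2.68 TPM with 79 of 82 expressed, histone genes chosen by symbol 1.37 ± 0.226 TPM with 34 of 71 expressed, and structural small RNAs 118 ± 13 TPM with 5 of 7 expressed.

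**Figure D1:**
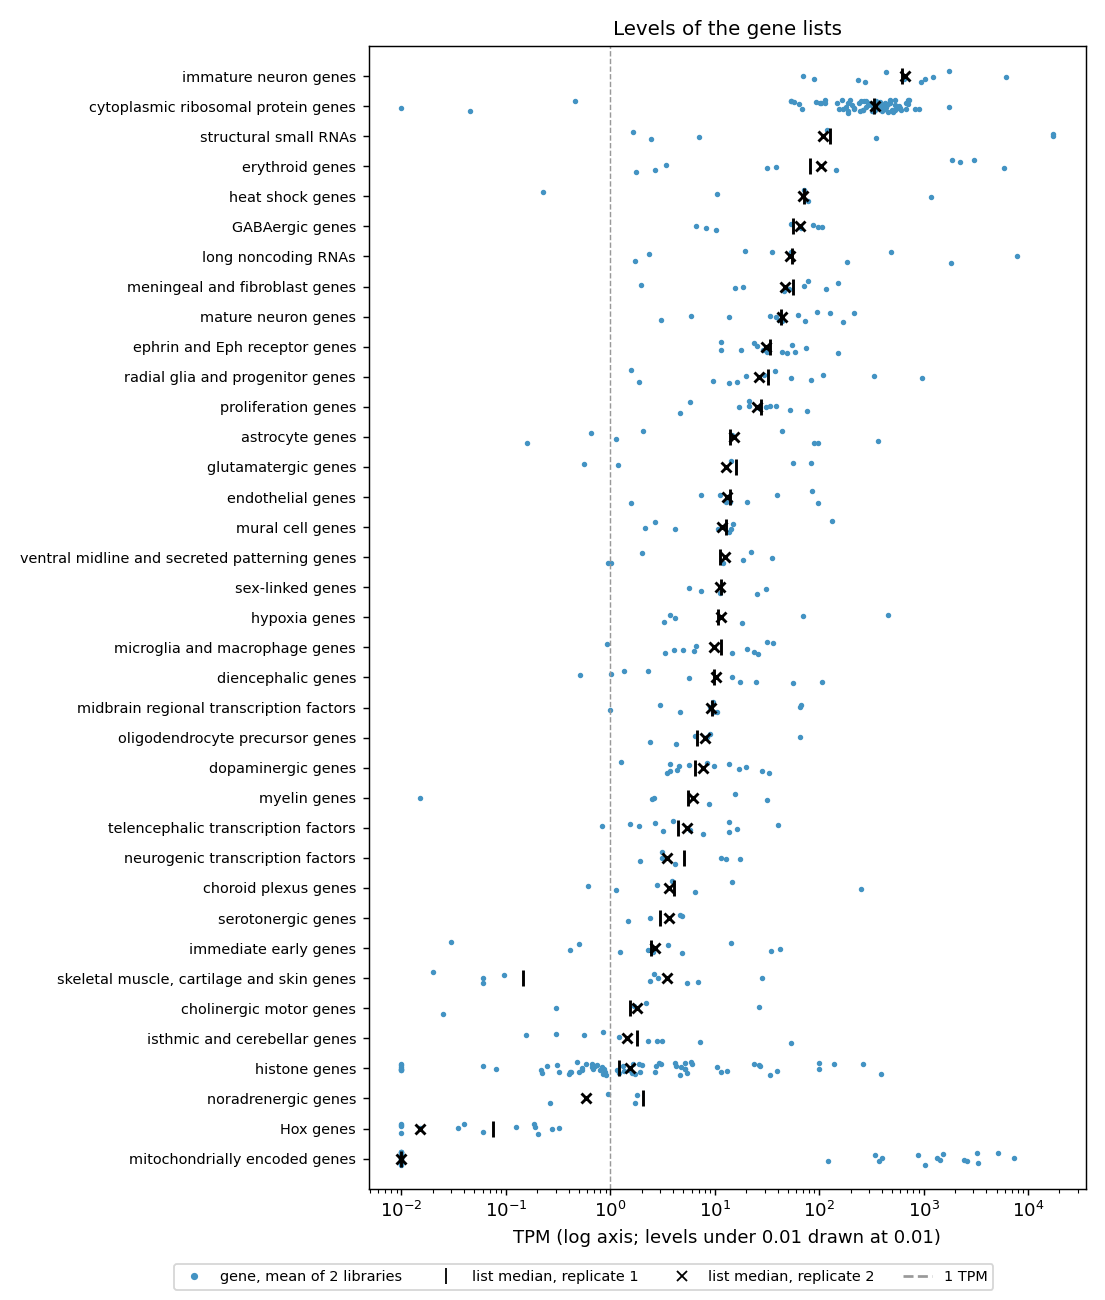
Levels of the gene lists on a log axis in TPM: points are genes (mean of 2 libraries), the vertical bar and the cross are the list median in replicate 1 and in replicate 2, and the dashed line marks 1 TPM. Immature neuron genes have the highest median over all members of a list (643 ± 27.4 TPM), and Hox genes lie below 1 TPM. The median over all 37 mitochondrially encoded genes is 0, and over the 15 of them that were expressed it is 1372 ± 194 TPM.

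Transcript tables allowed isoforms to be compared. Of 10301 expressed genes with more than 1 listed transcript, 9450 (91.7%, 95% Wilson interval 91.2 to 92.3) had the same most abundant transcript in both libraries. Pkm, the pyruvate kinase gene, has mutually exclusive exons on chromosome 9 (mm10). Transcript Pkm-202, with the exon at 59675029 to 59675195, took 67.5 ± 2.97% of the gene's abundance, and Pkm-201, with the exon at 59675568 to 59675734, took 32.5 ± 2.97%. For the synaptic fusion gene Snap25 on chromosome 2, transcript Snap25-201 with the exon at 136770057 to 136770174 took 88.1 ± 0.0849%, and Snap25-202 with the exon at 136769743 to 136769860 took 10.4 ± 0.0141%; the annotated lengths of these transcripts differ (2116 and 1014 nt), so reads outside the exon weigh in. The leading transcripts of the microtubule-associated protein genes were Mapt-205 (45.5 ± 0.198%) and Map2-201 (38.2 ± 0.00707%). For the adhesion gene Ncam1 and the clathrin light chain gene Clta they were Ncam1-204 (73.4 ± 0.566%) and Clta-204 (69.6 ± 1.73%). For Dlg4, a postsynaptic scaffold gene, it was Dlg4-201 (40.9 ± 1.27%). In Gria2 a transcript annotated as retaining an intron, Gria2-206, led with 45.4 ± 1.67%. Of the splicing regulators, Ptbp1-202 led with 33.7 ± 4.52% of Ptbp1, close to Ptbp1-216 (29.7 ± 2.54%), and Ptbp2 had 1 listed transcript at 142 ± 0.156 TPM. Transcript shares are estimates from reads that largely overlap between isoforms.

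The pools gave similar profiles. Over 16434 genes at 1 TPM or more in either library, log2(TPM + 1) correlated with a Pearson r of 0.986 and a Spearman rho of 0.989, across genes, which are not independent replicates. Among the 15347 expressed genes the SD of the log2 ratio was 0.20, and 98.5% of genes lay within 1.5-fold. That SD was 0.26 for genes under 3 TPM and 0.10 for genes at 100 TPM or more. The biological coefficient of variation was 0.0650. The counts of the libraries, which came from separate pools per the labels, differed by more than counting noise (chi-square 6.65 per gene over 18269 genes).

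**Figure D2:**
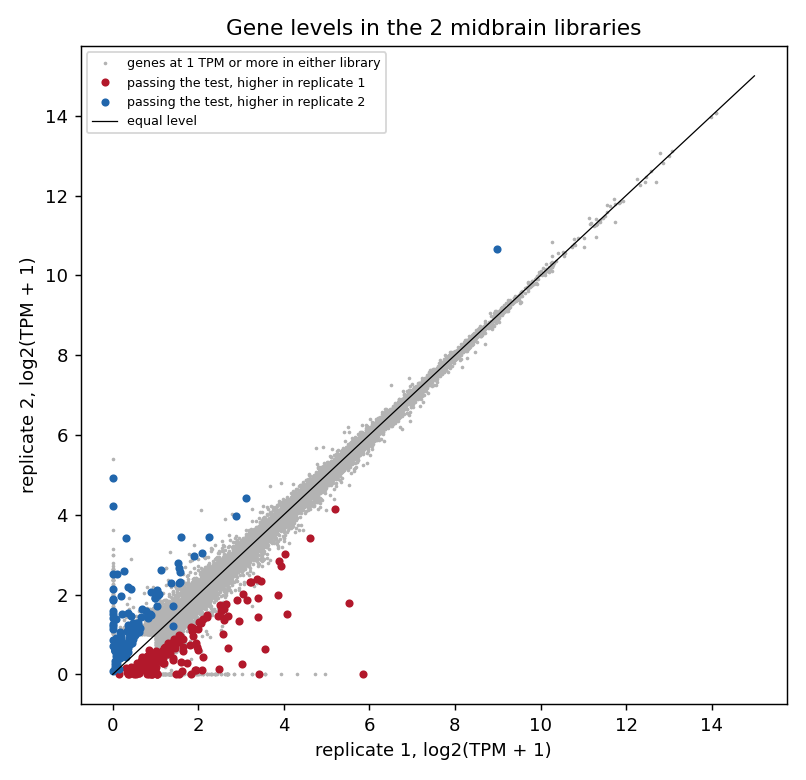
Level of each gene in replicate 1 (x axis) and replicate 2 (y axis), both in log2(TPM + 1): grey points are genes at 1 TPM or more in either library, red and blue points are genes that passed the binomial test and were higher in replicate 1 or replicate 2. Most points follow the line of equal level (r = 0.986), and the 283 passing genes lie mostly at low levels.

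Genes of tissues outside the brain were among those that differed most between the pools. Alb, the liver's serum albumin gene (chromosome 5, 90460897 to 90476602), was higher in replicate 1, 54.0-fold (95% counting interval 20.8 to 199.9) with 209 against 4 counts, and so was the liver protease inhibitor gene Serpina1b, 51.1-fold (95% counting interval 13.8 to 428) with 99 against 2 counts. The epidermal keratin genes Krt5 (chromosome 15, 101707070 to 101712898) and Krt14 were higher in replicate 2, 57.6-fold (95% counting interval 22.2 to 213) with 238 against 4 counts and 34.1-fold (95% counting interval 14.3 to 106) with 176 against 5. Noradrenergic genes were higher in replicate 1, with the transmitter-synthesising enzyme gene Dbh at 5.63-fold (95% counting interval 3.82 to 8.55) and the noradrenaline transporter gene Slc6a2 at 3.94-fold (95% counting interval 3.17 to 4.94). In all, 283 of 18269 tested genes (1.55%) passed the exact binomial test with Benjamini-Hochberg adjustment, 156 higher in replicate 1 and 127 in replicate 2; adjusted p by that exact test was 2.9e-55 for Alb and 1.4e-60 for Krt5. Without a fold threshold 3473 passed, and in simulated data 4493 unchanged genes did. The simulation gave every gene the same coefficient of variation (0.0650), estimated from these 2 libraries with all their differences taken as noise. It therefore cannot show how many of the 3473 differ by more than noise.

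The largest ratios were taken in equal number from each direction among passing genes with a mean of 50 or more counts. Of the 10 genes so chosen, all but Alb, Krt5 and Krt14 had ambiguous read assignment. Rpl30-ps10 and Gm10233, processed pseudogenes, and Gm26702, a long noncoding RNA, had 331, 179 and 108 counts in replicate 1 and 0 in replicate 2, but their posterior mean counts were 145 against 39.1, 168 against 54.0 and 119 against 18.2. The processed pseudogenes Gm4294 and Gm12191 had 0 counts in replicate 1 and 221 and 175 in replicate 2, with posterior means of 640.3 against 1148 for Gm4294 and, in the opposite direction, 117 against 85.9 for Gm12191. The gene ENSMUSG00000090407, for which no symbol was matched, had 6 against 271 counts and posterior means of 116 against 179. The size of the ratios of these 6 genes therefore rests on how ambiguous reads were assigned, whereas Serpina1b kept 98.5 against 2.30. Of 911 tested genes with ambiguous reads 109 passed (12%), against 174 of the 17358 others (1.00%). Under a rule that required the ratio to exceed 4 times the spread of 500 genes of similar level, 101 genes passed in place of 283.

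Among members of the gene lists, 13 of 410 tested passed, and 14 passed adjusted over the list alone. Besides Krt5, Krt14, Dbh and Slc6a2 these included Hoxb5 (8.26-fold, 95% counting interval 2.51 to 42.9), Hoxa5 (22.7-fold, 95% counting interval 3.67 to 938), the cortical homeobox gene Emx1 (2.39-fold, 95% counting interval 1.62 to 3.60) and the Purkinje cell gene Pcp2 (2.32-fold, 95% counting interval 1.34 to 4.16), all higher in replicate 1. The hypothalamic gene Sim1 (2.18-fold, 95% counting interval 1.78 to 2.67) and Chat, the acetylcholine-synthesising enzyme gene (2.81-fold, 95% counting interval 1.33 to 6.46), were higher in replicate 2. The histone genes Hist1h2ai, higher in replicate 1, and Hist1h2ad, higher in replicate 2, passed over all genes, and Hist1h2bg, higher in replicate 2, over the list alone; all 3 had ambiguous read assignment.

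Most whole lists shifted by small amounts, and the Hox and noradrenergic lists by more. Relative to replicate 1, the median log2 ratio in replicate 2 was -0.24 for proliferation genes, with 11 of 11 lower, -0.13 for radial glia and progenitor genes (10 of 13 lower), -0.27 for neurogenic transcription factors (6 of 7) and -0.34 for astrocyte genes (7 of 8). Non-neural lists were lower as well, with -0.18 for meningeal genes (9 of 9), -0.24 for microglia (8 of 12) and -0.33 for erythroid genes (7 of 10). Midbrain regional factors (-0.26, 5 of 9 lower), glutamatergic genes (-0.24, 5 of 5), noradrenergic genes (-1.97, 3 of 3), histone genes (-0.14, 29 of 38) and the 3 Hox genes with enough counts (-2.85, 2 of 3) were also lower in replicate 2. Higher in replicate 2 were GABAergic (0.14, 7 of 8 higher), dopaminergic (0.10, 10 of 14), immature neuron (0.07, 8 of 11) and mature neuron genes (0.08, 9 of 13), as were sex-linked genes (0.19, 5 of 5), long noncoding RNAs (0.19, 8 of 9) and mitochondrially encoded genes (0.14, 14 of 15).

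These 19 of 37 lists, 12 lower and 7 higher, lay outside the middle 95% of random lists matched on mean count. If genes varied independently of each other, 1.85 lists would. Genes of a marker list can rise and fall together in a pool, so 1.85 is no chance rate for these lists. The other 18 lay inside that range, among them oligodendrocyte precursor (-0.02), myelin (-0.07), endothelial (-0.08), mural (-0.10), choroid plexus (0.07), telencephalic (-0.14), diencephalic (-0.01), isthmic and cerebellar (-0.15), serotonergic (0.14) and cholinergic motor genes (0.20). The rest were patterning (0.12), ephrin (0.02), muscle, cartilage and skin (0.13), immediate early (-0.02), heat shock (0.02), hypoxia (0.05), structural small RNA (-0.04) and ribosomal protein genes (-0.0012). For 5 of the 19 the median level went the other way, from 81.3 to 103 TPM for erythroid, 14 to 15.3 for astrocyte, 1.21 to 1.53 for histone, 11.5 to 11.2 for sex-linked and 55.4 to 53.0 for long noncoding genes. On TPM ratios the dopaminergic, glutamatergic, immature neuron and sex-linked lists fell inside the range. Once GC and length trends were removed, immature neuron (0.04), mature neuron (0.05), sex-linked (0.10, 3 of 5 higher) and histone genes (-0.09) fell inside it. Endothelial genes moved outside it with those trends removed (-0.09, 8 of 10 lower in replicate 2).

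**Figure D3:**
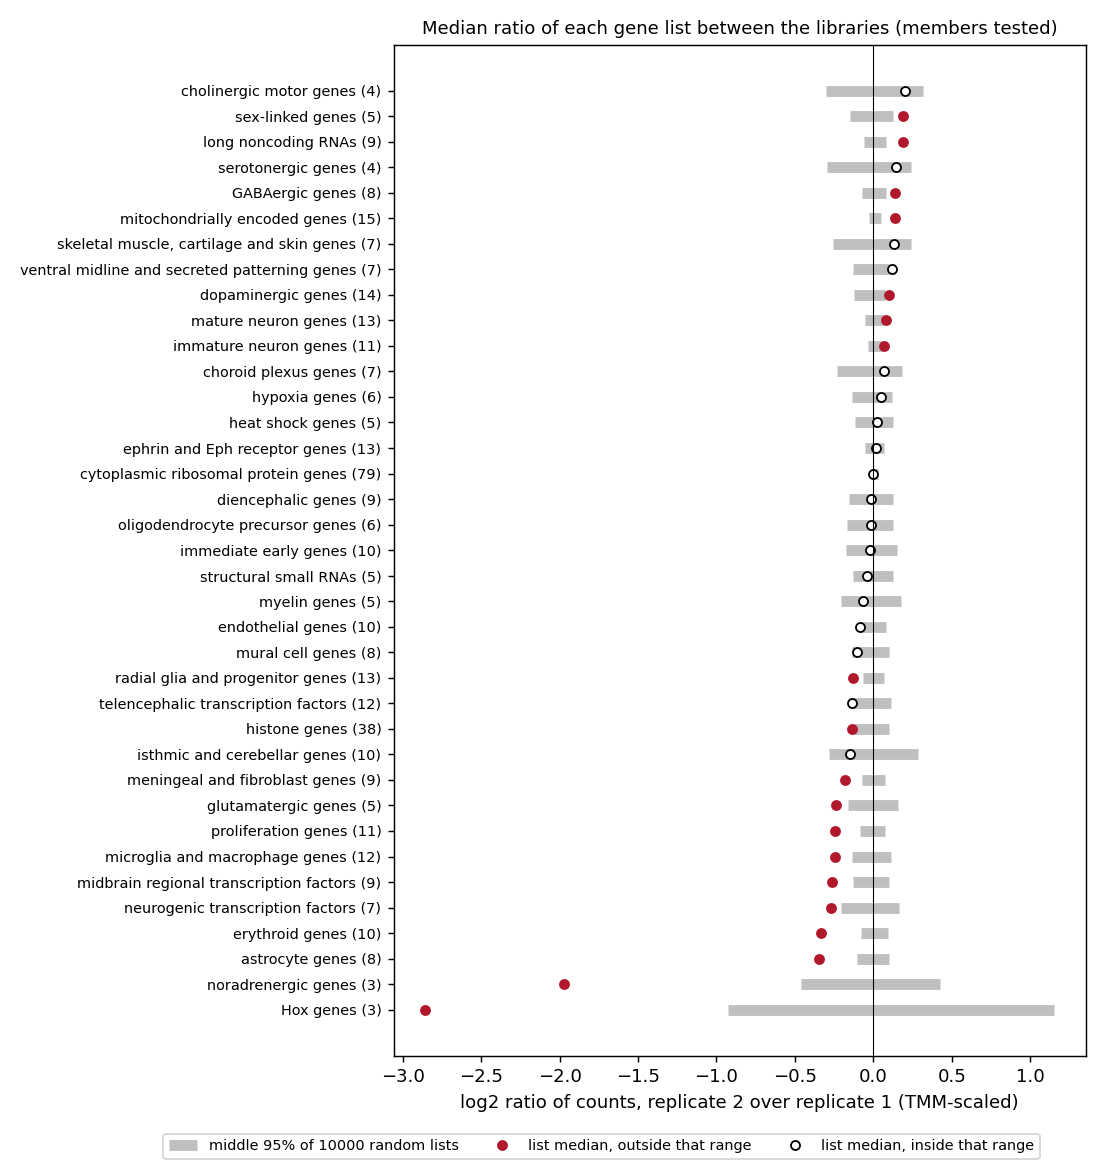
Median log2 ratio of counts (replicate 2 over replicate 1) of each gene list, with the number of tested members in parentheses: filled points lie outside, open points inside, the grey bar, which is the middle 95% of 10000 random lists of like mean count. Hox (-2.85) and noradrenergic genes (-1.97) stand farthest to the left, and the other lists lie between -0.34 and 0.20.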

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

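Reads were also assigned to rows that no comparison used. The rows with only a number as ID held 21.38 expected counts in replicate 1 and 12 in replicate 2, in 7 rows each, where a count of 0 allows up to 3. Of these rows 63 were long enough (100 nt or more) to take a read. What the features are is not given in the sources used here, and no explanation was tested.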

How the results depend on the processing

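The posterior mean counts, the restriction to genes without ambiguous reads and the removal of GC and length trends were chosen after the results were seen; the other alternatives were fixed before. Expressed genes ranged from 11426 (5 TPM or more) to 20559 (0.1 TPM or more), and from 15881 to 15900 in a single library. Pearson's r moved to 0.955 with a pseudocount of 0.1, 0.995 without a filter, 0.987 at 5 TPM or more and 0.994 with posterior mean TPM; Spearman's rho was 0.954, 0.992 and 0.990 in the last 3. The SD of the log2 ratio moved to 0.24 with a pseudocount of 0.1, 0.15 at 5 TPM or more, and 0.16 on counts scaled by TMM (0.161) or by DESeq2 size factors (0.161). Genes differing between the libraries moved from 283 to 67 at a mean of 50 or more counts, 506 at 1.5-fold, 3473 without a fold threshold, 101 under the spread of similar genes and 173 without ambiguous reads, where fewer genes were tested or the criterion was other; DESeq2 size factors, total counts, no count filter and posterior mean counts gave 282, 282, 348 and 262. Lists outside the random range numbered 17 on TPM ratios (15 of them as before), 19 with members of 50 or more counts (17 as before), 18 without ambiguous reads (18 as before) and 16 without GC and length trends (15 as before). Diencephalic genes turned from -0.01 to 0.41 with members of 50 or more counts, of which there were fewer. Contrasts of lists moved as follows, in log2 units. With a pseudocount of 0.1, midbrain minus Hox was 6.06, dopaminergic minus serotonergic 1.10, precursor minus myelin 0.52 and endothelial minus mural 0.15. Over expressed members, GABAergic minus glutamatergic was 1.05, immature neuron minus microglia 5.38, precursor minus myelin -0.23 and radial glia minus astrocyte -0.57; midbrain minus Hox had no value, as no Hox gene was expressed. With list means, the values were 1.59 for GABAergic minus glutamatergic, 1.16 for dopaminergic minus serotonergic, 4.03 for immature neuron minus radial glia, 3.66 for immature minus mature neuron, 0.60 for precursor minus myelin, 0.70 for endothelial minus mural and 5.64 for immature neuron minus microglia. Each contrast kept its sign in either library alone. The same top transcript was found in 94.6% of genes at 10 TPM or more and in 97.7% where it led by 20 points. On expected counts the 10 highest genes took 5.26%, mitochondrially encoded genes 1.5% and spike-ins 2.36%, against 10.1%, 3.15% and 5.76% of TPM. Where no cause is given, the cause was not tested. Results that compare the libraries need both, so neither could be left out there, and 2 pools limit every SD given.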

Other observations

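All gene groups and tests in this part were chosen after results were seen, apart from those named next. The summed counts of further organ genes and the count of 8 lists after the removal of GC and length trends were set down beforehand. Of 23 imprinted genes matched, all 23 were at 1 TPM or more in both libraries, with Nnat at 8766 ± 155 TPM, the noncoding RNA Meg3 at 1847 ± 117, the neuronal growth suppressor gene Ndn at 1496 ± 4.99, Gnas at 1115 ± 3.41 and Snrpn at 744 ± 10.7 (mean ± SD, n = 2), and together they took 1.29% and 1.34% of the gene counts. Tubulin genes, 13 of 15 expressed, took 2.5% and 2.44%, and after Tuba1a the highest were Tubb2a (2628 ± 62.6), Tubb3 (1757 ± 36.6), Tubb5 (1517 ± 11.9) and Tubb2b (1089 ± 8.03).

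Of 24 neuropeptide and granule protein genes 20 were at 1 TPM or more in both libraries. The somatostatin gene Sst was highest at 278 ± 10.7 TPM, followed by Chga (122 ± 0.955), Npy (102 ± 29.5), Scg2 (101 ± 3.46) and Tac1 (82.6 ± 4.41), of which Npy and Tac1 encode the precursors of neuropeptide Y and substance P. All 18 axon guidance receptor genes were expressed, with Robo2 (75.2 ± 1.68), Plxna1 (57.0 ± 1.43), Plxna3 (56.9 ± 5.62) and Robo1 (41.2 ± 0.70) highest. The commissural receptor gene Robo3 was the 1 member that passed the test between the pools, with 748 counts in replicate 1 and 378 in replicate 2. Embryonic globins (Hbb-y, Hba-x and Hbb-bh1) made up 1.19% of globin counts in replicate 1 and 2.14% in replicate 2.

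Some genes of other organs differed between the pools. The liver genes first seen (Alb, Afp, Apoa2, Serpina1b, Fgg, Ahsg, Fga and Fgb) summed to 979 counts in replicate 1 and 46 in replicate 2, the heart genes (Actc1, Tnnt2, Myl4 and Myh6) to 1850 and 156, the granulocyte genes (S100a8, S100a9, Camp and Elane) to 253 and 31, the keratinocyte genes (Krt5, Krt14 and 7 others) to 71 and 809, and the pancreas genes (Pnliprp1 and Ctrb1) to 5 and 144. Their levels were low, with Actc1, the highest, at 44.8 TPM in replicate 1 and 2.44 in replicate 2, Alb at 4.60 and 0.09, and Krt5 at 0.08 and 4.72. Reads shared with copies do not account for this, since 3.70% of these 27 genes had ambiguous assignment. RNA of other organs in a pool was then tested on further list members, recorded as not looked at before. That record may not hold for all of them. Kng1, a further liver gene with 20 against 0 counts, ranked by log2 ratio above Afp (329 against 9), a gene first seen. The summed counts of the further members were higher in the same pool for each list. The ratio was 1.34-fold for liver (95% counting interval 1.27 to 1.42), 2.02-fold for heart (1.79 to 2.28) and 1.44-fold for granulocyte genes (1.21 to 1.71). It was 1.07-fold for keratinocyte (1.01 to 1.14) and 1.31-fold for pancreas genes (1.04 to 1.65). For carry-over at least 4-fold had been predicted, and an upper bound under 2-fold had been set beforehand as evidence against it, so the predicted size was reached by none of the 5 sums, and all but the heart genes met the bound against carry-over. The bound was a poor one, because 93.6%, 92.2%, 74.2%, 90.9% and 63.5% of those sums in the lower library came from members at 1 TPM or more in both libraries, such as Trf with 1808 and 1413 counts.

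Only after that outcome was a test by single members chosen, so it weighs less. Of the tested liver genes 41.2% (7 of 17, among them Serpina1a with ambiguous reads) passed in replicate 1. So did 60% of the heart genes (6 of 10) and 40% of the granulocyte genes (2 of 5), against 0.854% of all genes and with 0 passing the other way in each list. This goes with RNA of these organs in that pool, in contrast to the sums. It is no independent support, because the pattern was itself seen among genes that passed the test between the pools. For keratinocytes (7.14%, 1 of 14) and pancreas (25%, 1 of 4, with ambiguous reads) this test left it open. Carry-over at dissection and mixing between samples were not separated, and no biological explanation was tested.

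GABAergic, dopaminergic, immature and mature neuron lists were higher, and progenitor, proliferation, neurogenic and astrocyte lists lower, in replicate 2; these 8 were picked for that pattern, and the glutamatergic (-0.24) and noradrenergic lists (-1.97) were lower there too. Removing the trends of the log2 ratio on GC content and length (Spearman's rho -0.204 and 0.111 across the 99.1% of tested genes with a GC value) left 6 of the 8 lists outside the random range, 4 of 4 progenitor and astrocyte lists and 2 of 2 for the GABAergic (0.14 to 0.12) and dopaminergic lists (0.10 to 0.14), so this bias does not account for these. For the immature and mature neuron lists, with 0 of 2 left outside, it stays open, since immature neuron genes went from 0.07 to 0.04 and mature neuron genes from 0.08 to 0.05, which ended both calls while more than 0.5 of each shift remained. More non-neural tissue in replicate 1 would dilute immature neuron and radial glia genes alike only if non-neural cells express neither list, which was not tested. The medians of these lists differed by -0.20, outside the -0.10 to 0.07 of random pairs. The pattern was seen from these same lists, picked for having moved apart, so their difference cannot decide about that explanation. Other lists were not tested this way. Meningeal (-0.18), microglia (-0.24) and erythroid genes (-0.33) were lower in replicate 2, which goes with that explanation. Endothelial (-0.08) and mural genes (-0.10) lay inside the random range. Choroid plexus (0.07) and muscle, cartilage and skin genes (0.13), also inside it, were higher in replicate 2. Choroid plexus cells need not count as non-neural tissue, so that list weighs less. With GC and length trends removed, endothelial genes fell outside the range, lower in replicate 2 (-0.09, 8 of 10 lower). That also goes with more non-neural tissue in replicate 1. The mural, choroid plexus, and muscle, cartilage and skin lists stayed inside. Older embryos in replicate 2 cannot be told apart from the rest: the log2 ratio of embryonic to adult globin counts was higher there by 0.86, opposite to what age would give, but erythroid genes as a list were lower (-0.33), and the blood in the pools may differ for reasons of its own.

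Among genes that passed between the pools, 32 had 0 counts in one of them. Reads shared between near-identical copies are a candidate explanation, as 84.4% of them (27 of 32) had ambiguous assignment, against 911 of all 18269 tested genes. With posterior mean counts the library at 0 had more than 3 counts for 25 of those 27. The exceptions were the liver genes Serpina1a (53.4 against 0.32) and Serpina1e (22.4 against 0.14), both higher in replicate 1. Over the 27 genes the median fold went from 58.9 to 3.20 (quartiles 2.23 and 4.50), and 1 gene reversed. For most of the 27 the 0s and the size of the differences therefore rest on read assignment. Since 19 of the 27 still passed in the same direction, this explanation and a smaller true difference cannot be told apart; which copy a read came from was not analysed here. A more abundant gene with ambiguous reads and no count of 0, the mitochondrial-like pseudogene Gm10925, had 6855 expected counts in replicate 1 and 22485 in replicate 2, but posterior means of 21531 and 30278. No biological explanation was tested.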
